A study of Mus musculus with 6 samples.

How the data were processed

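Liver RNA of C57BL/6 mice, a common inbred laboratory strain, was measured on 6 Affymetrix mouse arrays, 3 from mice on a high-fat Western-style diet and 3 from mice on a low-fat diet. The diets were given for 12 weeks, per the labels. The diet and the number of each array were taken from its title. The labels call the 3 arrays of a diet replicates but do not say whether each holds the RNA of 1 mouse or of a pool. P-values of single probe sets therefore measure the spread between these arrays.

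The deposited table holds 1 linear intensity for each of 12488 probe sets on each array, and all of these values are above 0. The software and background correction that the authors used are not given in the sources used here. The values themselves show that each deposited array had been scaled as a whole: the mean intensity without the lowest and highest 2% of probe sets was 500.4 on all 6 arrays. Array medians ran from 171.5 to 188.4. The number of arrays limits the precision, and a scaling of whole arrays cannot show a change that moves most transcripts in one direction.

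Probe sets were named through the platform's gene table, in which 10855 had 1 gene symbol, 396 had several and 1237 were not listed. Of the single-gene probe sets, 10839 were matched by gene ID to the RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. No coordinates are given, because no genome build is named for the probe sets. No gene was named from a probe set with several symbols. The genes named as checks in the fixed rule included 2 with no probe set in the gene table used, and these are not analysed here.

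The deposited scaling was kept, because the trimmed means agreed within 5%. Values under the pooled 30th percentile of all intensities, 68.9, were set to that floor and log2 was taken. A probe set was tested when at least 3 of the 6 arrays lay above the floor. The 66 control probe sets were left out, and 8950 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on intensity), as high-fat minus low-fat diet, two-sided. P-values were adjusted by the method of Benjamini and Hochberg and the threshold was an adjusted p of 0.05. Adjusted p-values of single genes are limma's throughout. Folds are ratios of means on the floored log2 scale, so they understate the change of genes near the floor. Group means and SDs are of the deposited intensities. For each gene, the single-gene probe set with the highest mean log2 value was used, which left 6557 genes.

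A set of 35 gene lists for liver metabolism, stress and cell types was fixed before the data were examined, as were the test, the floor, the filter and the alternatives named here. The 33 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera compares a list with all other genes. At the preset correlation its p-values rest mainly on the spread between genes, treated as nearly independent, and not on that between arrays. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move on balance in one direction. The named genes follow a fixed rule. They are the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays of both diets did not overlap, and for each list described up to 4 members past the threshold by smallest p. Where fewer than 2 members passed, the 2 with the smallest p are given as values. Other genes named are said to have been chosen after their values were seen.

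The method was tested on simulated data drawn at the spread of these 6 arrays, in 20 runs of 8950 probe sets with 200 changed for the comparison of high-fat with low-fat diet. It found 38.2% of probe sets changed by 1 on the log2 scale and 88.0% of those changed by 2, and 5.85% of the calls were false. A list of 16 genes shifted by 0.5 was found in 20 of the 20 runs. The simulated variances were drawn around a trend on intensity, with normal noise, as the test assumes. The runs therefore do not show how the calls fare where that model fails. The simulated genes varied independently of one another. Genes of the real acute phase list had an estimated correlation of 0.298, so the runs do not show how the list test fares on correlated genes.

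Alternatives were quantile normalization, scaling to a common median, floors at the 10th and 50th percentile, an added constant in place of the floor, no filter, a filter asking for all 6 arrays, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, each array left out in turn, probe sets with suffixes for shared probes left out, and an adjusted p of 0.10. For the lists they also included the mean over all probe sets of a gene. The suffixes left out included that for relaxed probe selection, which does not mark shared probes. Comparisons of single values between diets used an exact two-sided permutation test, which with 3 arrays against 3 cannot give a p under 0.1.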

Results

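Transcript levels were measured in the livers of C57BL/6 mice that had been fed for 12 weeks with a high-fat Western-style diet or with a low-fat diet. Each diet had 3 arrays, and the single comparison of the study asks which liver transcripts differ between the diets. Between 8513 and 8813 of the 12488 probe sets lay above the floor intensity of 68.9 on an array. Log2 values of the arrays correlated across probe sets with r from 0.948 to 0.962 within a diet and from 0.937 to 0.962 between diets, where probe sets are not independent replicates. The control probe sets for Gapdh, read at both ends of the transcript, gave a 3' to 5' ratio of 1.12 ± 0.20 (SD, n = 3) on the high-fat diet and 0.98 ± 0.13 (SD, n = 3) on the low-fat diet. The difference between the diets did not pass an exact permutation test (p = 0.3, where 0.1 is the smallest that 3 arrays against 3 allow), and the same test gave 0.3 for beta-actin. The 3' to 5' ratio of pyruvate carboxylase was 5.84 ± 2.83 (SD, n = 3) on the high-fat and 3.64 ± 0.93 (SD, n = 3) on the low-fat diet (exact permutation p = 0.4). The lowest Gapdh ratios were those of the arrays numbered 3, at 0.89 on the high-fat and 0.82 on the low-fat diet.

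On the high-fat diet, transcripts for lipid storage were higher as a list, and those for cholesterol synthesis were lower. The steepest rises among named genes were those of Cidea, which encodes a lipid droplet protein, at 22.5-fold, and of the apolipoprotein gene Apoa4, at 11.7-fold. With 1 probe set per gene, the steepest falls were those of the cholesterol synthesis genes Sqle, 13.9-fold lower, and Idi1, 8.12-fold lower. A further probe set of Usp2, not the one used for that gene, was 14.5-fold lower. In all, 74 of 8950 tested probe sets passed an adjusted p of 0.05, of which 36 were higher and 38 lower on the high-fat diet, and 53 of the 74 differed by at least 2-fold. With 1 probe set per gene, 60 of 6557 tested genes passed, 30 higher and 30 lower. In all 60 the arrays of the diets did not overlap, which is no separate support, since the same values gave the calls. Of all tested genes, 14.5% had arrays that did not overlap, where chance gives 10%. An unadjusted p under 0.05 was reached by 812 probe sets, against 448 by chance. The number of calls depended on the model and on single arrays: it was 20 without the trend of the variance on intensity and 8 without a filter on dim probe sets. It was 28 without high-fat array 2, 31 without low-fat array 1, 26 without low-fat array 2 and 45 without low-fat array 3, and without high-fat array 3 the calls higher on the high-fat diet numbered 23.

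The list fixed for cholesterol synthesis and uptake was lower on the high-fat diet, and all 16 of its measured members encode enzymes of synthesis, none of uptake. Of these 16, 9 fell, 7 did not pass the test, and all 16 had a fold change below 0, with a median log2 fold change of -1.22, and 15 fell adjusted over the list alone. The list was shifted with an adjusted p of 8.49e-30, and with an adjusted p of 0.0154 with an estimated correlation. Squalene epoxidase, encoded by Sqle, acts on the pathway from squalene to sterols, and its intensity was 230 ± 146 (SD, n = 3) on the high-fat diet against 2860 ± 661 (SD, n = 3) on the low-fat diet. Idi1, the isopentenyl diphosphate isomerase, fell from 4272 ± 146 (SD, n = 3) to 531 ± 86.4 (SD, n = 3), a log2 change of -3.02 ± 0.14 (SE) with an adjusted p of 4.78e-05. The sterol methyl oxidase gene Msmo1 was 5.79-fold lower (adjusted p = 0.00242), and the farnesyl diphosphate synthase gene Fdps was 3.35-fold lower (adjusted p = 0.00128). A second Fdps probe set also fell, as did each of the other probe sets of Nsdhl. Cyp51 was 3.85-fold lower and Nsdhl 3.60-fold lower, with adjusted p-values of 0.0217 and 0.0271. The calls of Sqle, Idi1, Msmo1 and Fdps held with each array left out in turn. Those of Cyp51 and Nsdhl did not: the call of Cyp51 was lost without high-fat array 2 or without any of the low-fat arrays, and that of Nsdhl without high-fat array 1, high-fat array 2 or low-fat array 1.

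**Figure D1:**
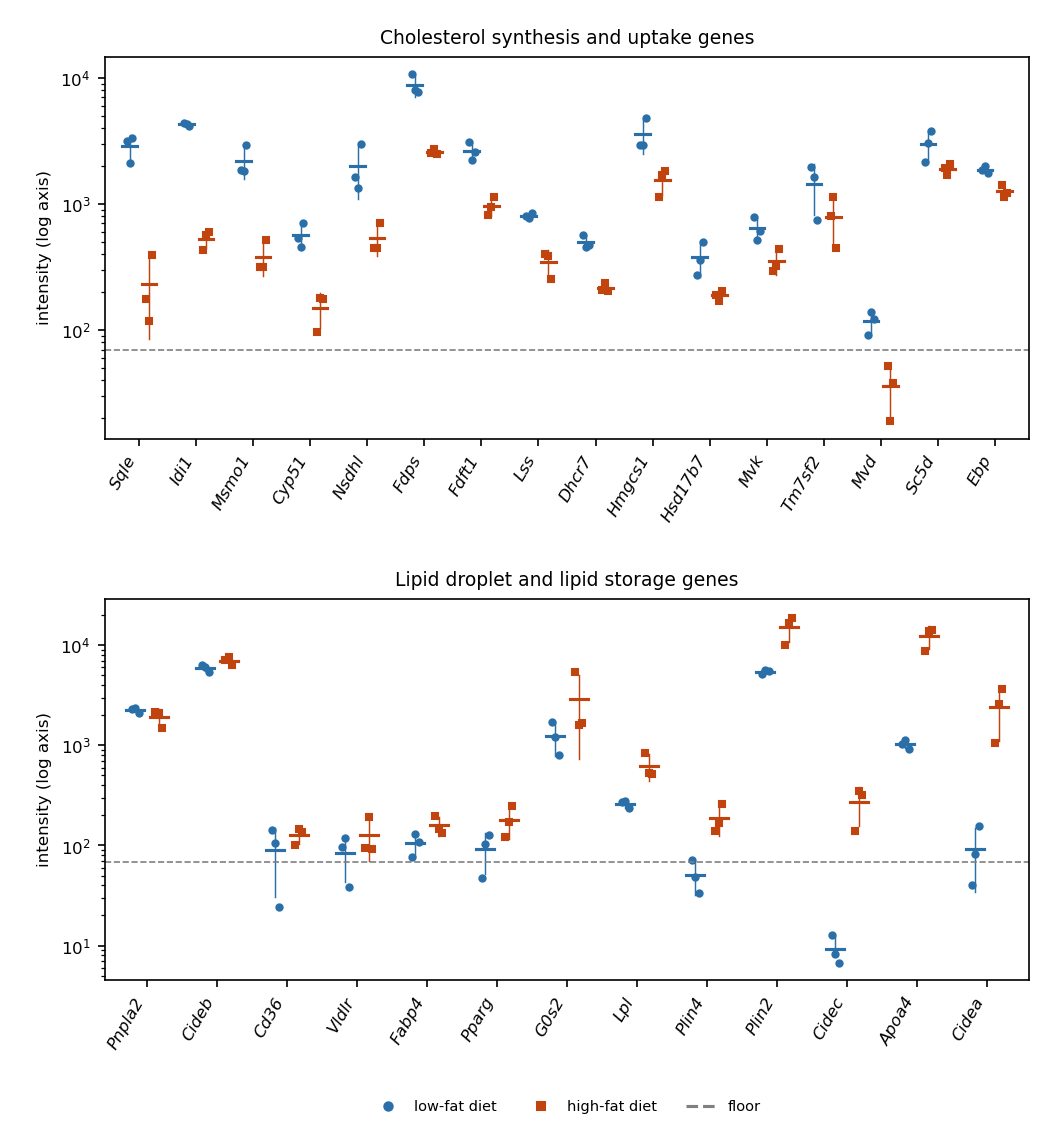
Intensity (log axis) of each tested gene of cholesterol synthesis and uptake (top) and of lipid droplets and lipid storage (bottom) on the 3 low-fat (circles) and 3 high-fat arrays (squares), with horizontal bars for means, vertical bars for 1 SD and a dashed line at the floor of 68.9. Sqle lies near 2860 on the low-fat and 230 on the high-fat diet, and Apoa4 near 1032 and 12312; points below the floor were set to it in the test.

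The lipid droplet and lipid storage genes were higher as a group. Of 13 measured members 3 rose and 10 did not pass the test, 12 had a fold change above 0, and the median log2 fold change was 1.05. There were 6 that rose adjusted over the list alone. The list's adjusted p was 2.90e-11, and 0.0336 with an estimated correlation. Cidea had an intensity of 2434 ± 1320 (SD, n = 3) on the high-fat diet and 92.4 ± 58.2 (SD, n = 3) on the low-fat diet, where 1 array lay at the floor. Its log2 change was 4.49 ± 0.45 (SE), with an adjusted p of 0.00258. Plin2, which encodes the main coat protein of liver lipid droplets, rose 2.71-fold from 5396 ± 233 (SD, n = 3) to 15069 ± 4396 (SD, n = 3), with an adjusted p of 0.0177. The remaining called member, Apoa4, encodes a secreted apolipoprotein and rose from 1032 ± 101 (SD, n = 3) to 12312 ± 3060 (SD, n = 3), with an adjusted p of 6.52e-05. The calls of Cidea and Apoa4 held with each array left out, and that of Plin2 was lost without high-fat array 2 or any of the low-fat arrays.

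Of the 29 measured genes of fatty acid oxidation and ketogenesis, 1 rose and 28 did not pass the test, while all 29 had a fold change above 0, with a median of 0.30, and 4 rose adjusted over the list alone. The list's adjusted p was 4.95e-10, and the adjusted p was 0.178 with an estimated correlation. The called member was Vnn1, a pantetheinase, which rose 3.85-fold (adjusted p = 0.0217), a call lost without high-fat array 2 or any of the low-fat arrays. Ehhadh, a peroxisomal oxidation enzyme, was 1.53-fold higher with an adjusted p of 0.0880. Among the 17 genes of fatty acid and triglyceride synthesis, 1 rose and 1 fell. Elovl5, a fatty acid elongase, rose 2.64-fold (adjusted p = 0.00242), and Lpin1, a phosphatidate phosphatase, fell with a ratio of 2.43 between the low-fat and the high-fat diet (adjusted p = 0.0325). Adjusted over the list alone, 2 rose and 1 fell. That list had a median log2 fold change of 0.23 and an adjusted p of 0.0325, with an adjusted p of 0.571 with an estimated correlation. Its call was lost without high-fat array 1, high-fat array 2, low-fat array 1 or low-fat array 2, where adjusted p-values were 0.126, 0.151, 0.0630 and 0.0671. With the Gapdh 3' to 5' ratio as a covariate, chosen after the data were seen, the adjusted p was 0.145. Lpin1 kept its call only without high-fat array 2.

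**Figure D2:**
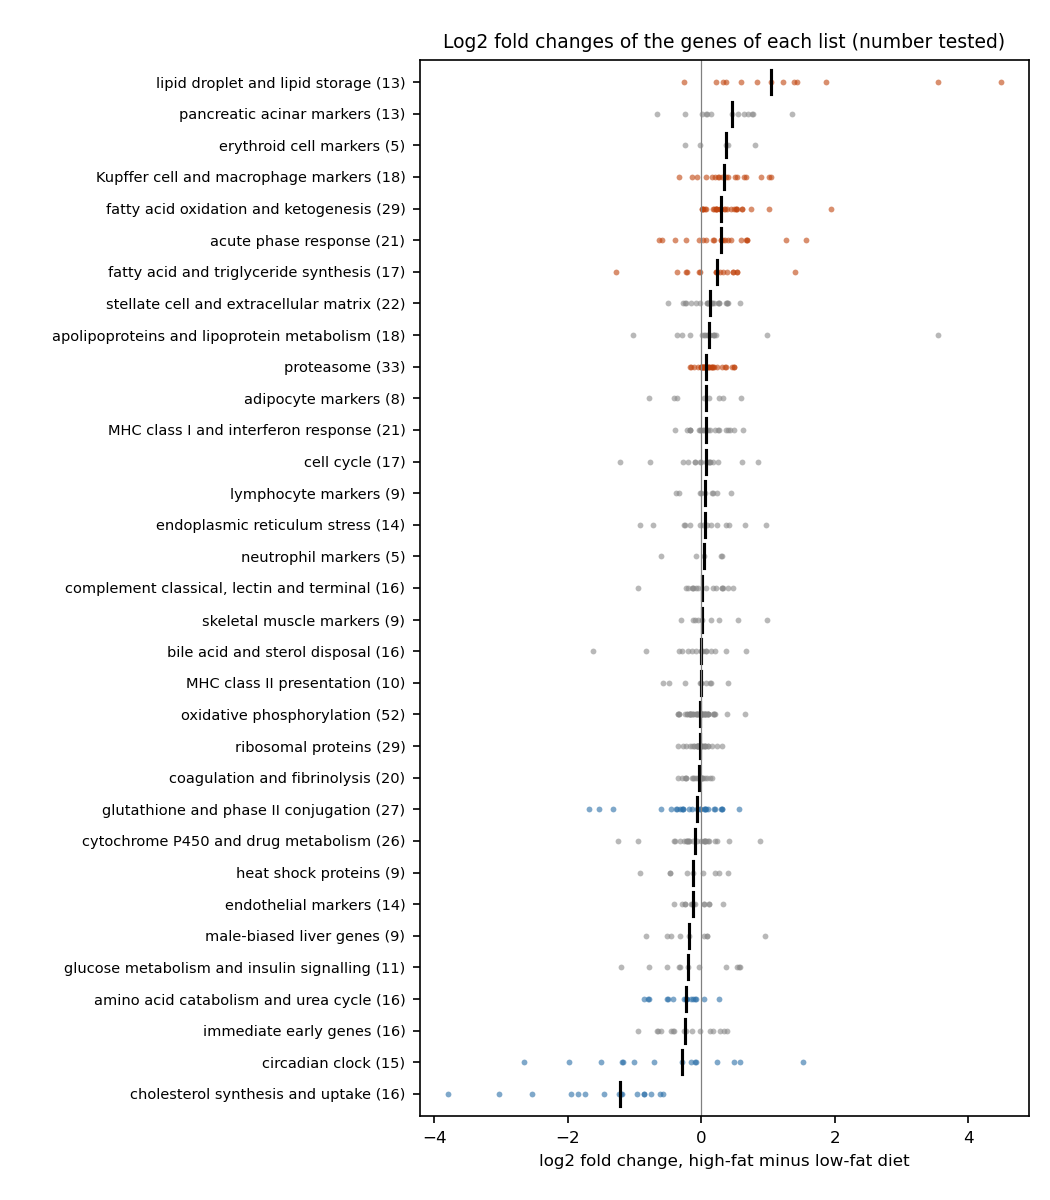
Log2 fold change, high-fat minus low-fat diet, of every tested gene (points) in the 33 gene lists, with a black bar at each list's median and the number of genes tested in brackets. Lists past an adjusted p of 0.05 in camera are orange where higher and blue where lower, others are grey; the medians run from -1.22 for cholesterol synthesis and uptake to 1.05 for lipid droplets.

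The list of genes of the circadian clock and its output was lower on the high-fat diet in camera, though its members moved in both directions. Of 15 measured members 3 fell and 12 did not pass, and 11 had a fold change below 0, with a median log2 fold change of -0.28. Adjusted over the list alone, 6 fell and 1 rose. The list's adjusted p was 0.00276, and 0.178 with an estimated correlation, while fry gave 7.85e-04. Fry also called the cholesterol and lipid droplet lists. The remaining lists called by camera did not pass in fry, with adjusted p-values from 0.0631 for fatty acid oxidation to 0.707 for acute phase. Without low-fat array 3 the median was -0.16 and the list kept its call (adjusted p = 0.00742). The clock output transcription factor gene Dbp was 6.29-fold lower, at 177 ± 59.7 (SD, n = 3) against 1074 ± 118 (SD, n = 3), with an adjusted p of 0.00242. The ubiquitin peptidase gene Usp2 was 3.94-fold lower and the core clock gene Per2 2.83-fold lower, with adjusted p-values of 0.0135 and 0.0287. The other Usp2 probe set was 14.5-fold lower (adjusted p = 0.00398), at 129 ± 89.6 (SD, n = 3) against 1705 ± 489 (SD, n = 3), with 2 of the 3 high-fat arrays above the floor. The call of Dbp held with each array left out, that of Usp2 was lost without high-fat array 2, and that of Per2 held only without high-fat array 3. Per2 had an adjusted p of 0.0547 with the Gapdh 3' to 5' ratio as a covariate. The labels give no time of day for tissue collection.

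**Figure D3:**
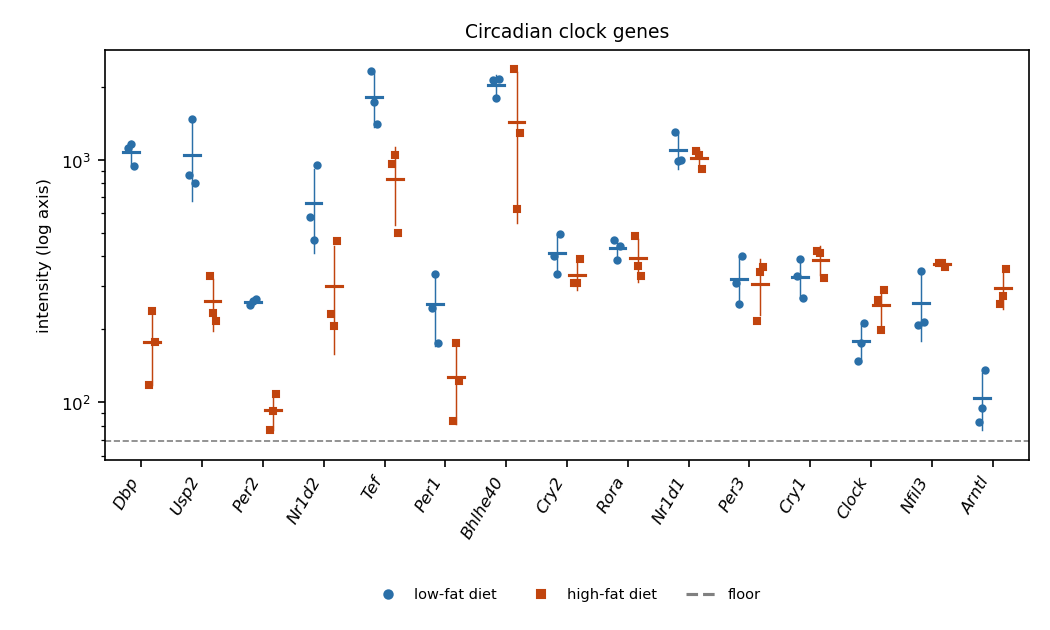
Intensity (log axis) of the 15 tested circadian clock genes on the 3 low-fat (circles) and 3 high-fat arrays (squares), with horizontal bars for means, vertical bars for 1 SD and a dashed line at the floor of 68.9. Dbp, Usp2 and Per2 are lower on all 3 high-fat arrays than on all 3 low-fat arrays, with Dbp at 177 against 1074.

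Of 27 measured glutathione and phase II conjugation genes 2 fell and 25 did not pass. The glutathione transferase genes Gsta2 and Gstt2 were 3.20-fold and 2.88-fold lower, with adjusted p-values of 7.52e-04 and 0.0177. Adjusted over the list alone, 3 fell. The list itself had a median of -0.06 and an adjusted p of 0.0495, with an adjusted p of 0.557 with an estimated correlation, and its call was lost without high-fat array 3 (adjusted p = 0.190), low-fat array 2 (0.181) or low-fat array 3 (0.0707). The median was -0.036 without high-fat array 1, -0.037 without high-fat array 3 and -0.12 without low-fat array 3. Gsta2 kept its call with each array left out, and Gstt2 lost it without low-fat array 1 or low-fat array 2. Of the 16 genes of amino acid catabolism and the urea cycle, 0 passed limma's test at an adjusted p of 0.05 and 14 had a fold change below 0, with a median of -0.23. Adjusted over the list alone, 1 fell. The list's adjusted p was 0.00108, and the adjusted p was 0.571 with an estimated correlation. The tyrosine aminotransferase gene Tat had a ratio of 1.73 between the low-fat and the high-fat diet (adjusted p = 0.0742) and the tryptophan dioxygenase gene Tdo2 a ratio of 1.43 (adjusted p = 0.319). The list lost its call without high-fat array 3 (adjusted p = 0.05001), where its median was -0.13.

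Markers of Kupffer cells and macrophages, the resident phagocytes of the liver, were shifted upward as a list with 0 of 18 measured members past limma's threshold. Their median log2 fold change was 0.34, 15 had a fold change above 0, and 1 rose adjusted over the list alone. The list's adjusted p was 0.00108, and the adjusted p was 0.633 with an estimated correlation. Mpeg1 was 1.86-fold higher (adjusted p = 0.0742) and Tyrobp 1.59-fold higher (adjusted p = 0.353). The acute phase list was also shifted upward, with 0 of 21 members past limma's threshold, 0 adjusted over the list alone, 16 above 0 and a median of 0.30. That list's adjusted p was 0.0325, and the adjusted p was 0.807 with an estimated correlation. The serum amyloid genes Saa2 and Saa3 had adjusted p-values of 0.465 and 0.180, and Saa2 stood at 1484, 7542 and 9235 on the high-fat arrays 1, 2 and 3 against 2330, 1589 and 1078 on the low-fat arrays. Without high-fat array 3 the median of the macrophage list was 0.22 with an adjusted p of 0.05001, and that of the acute phase list was 0.06 with an adjusted p of 0.749, and the acute phase call was also lost without low-fat array 2 (0.0899) or low-fat array 3 (0.0945). With both arrays numbered 3 left out, chosen after the data were seen, the adjusted p was 0.191 for the macrophage and 0.783 for the acute phase list. Proteasome genes had a median of 0.08, with 0 of 33 called, 0 adjusted over the list alone and 26 above 0. Their adjusted p was 0.0358, and the adjusted p was 0.738 with an estimated correlation. Psmd4 and Psma5 were 1.40-fold and 1.27-fold higher, with adjusted p-values of 0.307 and 0.389. The call of the proteasome list was lost without high-fat array 1 (0.0969), high-fat array 2 (0.0652), low-fat array 1 (0.123) or low-fat array 3 (0.389). Its median was 0.03 without low-fat array 1 or low-fat array 3 and 0.17 without low-fat array 2. With the Gapdh 3' to 5' ratio as a covariate its adjusted p was 0.282.

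Of the remaining named rises, Fabp2, a fatty acid binding protein, was 3.43-fold higher, Slc1a4, a neutral amino acid transporter, 4.69-fold, Denn2b 3.21-fold, Gadd45g 2.94-fold and the choline kinase gene Chka 2.64-fold. Their adjusted p-values were 0.0120, 0.0334, 0.0375, 0.0436 and 0.0157. The beta-tubulin genes Tubb2a and Tubb3 were 6.01-fold and 4.87-fold higher, with adjusted p-values of 0.00152 and 0.0173, on probe sets marked as shared within a gene family. The other probe sets of these genes had log2 fold changes of -0.09 and -0.27 and were not called, and that of Tubb3 is also marked as shared. Of the remaining falls, Upp2, a uridine phosphorylase, was 4.80-fold lower, at 3275 ± 922 (SD, n = 3) against 15283 ± 1283 (SD, n = 3). Noct, a rhythmic liver transcript, was 3.78-fold lower, and the transcriptional repressor gene Bcl6 3.38-fold lower. The 2 other tested probe sets of Noct had the same sign and were not called. The adjusted p-values of Upp2, Noct and Bcl6 were 0.00195, 0.0172 and 0.00242. Of the 32 named genes past the threshold, 12 kept their call with each of the 6 arrays left out, among them Tubb2a, Elovl5, Upp2 and Bcl6. Fabp2 lost its call without high-fat array 2, Chka without high-fat array 2 or low-fat array 2, Tubb3 without high-fat array 2, low-fat array 1 or low-fat array 2, and Noct without high-fat array 2, low-fat array 2 or low-fat array 3. Slc1a4 and Gadd45g kept theirs only without low-fat array 3, and Denn2b only without low-fat array 1.

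The other 23 lists tested did not pass with all 6 arrays. Apolipoproteins and lipoprotein metabolism had an adjusted p of 0.256 with 2 of 18 genes called, Apoa4 and the lipoprotein lipase cofactor gene Apoc2, which rose 1.99-fold (adjusted p = 0.0223). Cytochrome P450 and drug metabolism had an adjusted p of 0.178 with 1 of 26 genes called, Cyp2b10, which was 2.38-fold lower (adjusted p = 0.0173). Cyp3a25 had a ratio of 1.93 between the low-fat and the high-fat diet (adjusted p = 0.0579). Endoplasmic reticulum stress had an adjusted p of 0.692, with Creld2 1.96-fold higher (adjusted p = 0.0499) and Herpud1 at a ratio of 1.65 between the low-fat and the high-fat diet (adjusted p = 0.0587). The classical, lectin and terminal complement list had an adjusted p of 0.738, with C2 lower by a ratio of 1.92 (adjusted p = 0.0499) and C1qa 1.40-fold higher (adjusted p = 0.390). The cell cycle list had an adjusted p of 0.738, with a median of 0.07 and a mean of -0.01, and Tk1 was 1.69-fold lower (adjusted p = 0.0415), while its other probe set had a log2 fold change of 0.46 (adjusted p = 0.745) and Ccna2 had an adjusted p of 0.447. The calls of Creld2 and Tk1 were lost with any array left out and that of C2 with any but high-fat array 1. Apoc2 kept its call only without high-fat array 3 or low-fat array 3, and Cyp2b10 only without high-fat array 1 or high-fat array 3.

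Metabolic and housekeeping lists with 0 genes called were bile acid and sterol disposal (adjusted p = 0.738), coagulation and fibrinolysis (0.337), glucose metabolism and insulin signalling (0.291), oxidative phosphorylation (0.475), ribosomal proteins (0.475), heat shock proteins (0.738), immediate early genes (0.146) and male-biased liver genes (0.337). Lists of other cells and of immune functions with 0 genes called were lymphocytes (0.692), neutrophils (0.805), MHC class II presentation (0.777), MHC class I and interferon response (0.475), stellate cells and extracellular matrix (0.291), endothelium (0.478), adipocytes (0.692), pancreatic acinar cells (0.436), erythroid cells (0.337) and skeletal muscle (0.689). The acinar list had a median of 0.46, and the adipocyte list a median of 0.08 with a mean of -0.02. Without high-fat array 1, 7 of the 23 lists passed: stellate cells and extracellular matrix (0.0133, median 0.26), glucose metabolism (0.0133, median -0.30), oxidative phosphorylation (0.0211, median -0.08), cytochrome P450 (0.0215), immediate early genes (0.0255), male-biased genes (0.0262) and coagulation (0.0452, median -0.10). Acinar cells passed without high-fat array 3 (0.0158), the MHC class I list without low-fat array 1 (0.0122) and immediate early genes without low-fat array 2 (0.00399). Oxidative phosphorylation passed with the Gapdh 3' to 5' ratio as a covariate (0.00219, median -0.11). The alternative pathway of complement, with 4 genes tested, and bile duct epithelium, with 2, had too few genes and were not tested as lists.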

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

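The alternatives that use the arrays numbered 3 or the Gapdh 3' to 5' ratio were chosen after the data were seen, as was the fit without probe sets at the floor on all arrays, the others before. All 32 named genes past the threshold kept their direction wherever they were tested, and no result reversed. Quantile normalization gave 74 probe sets, as many as the reported setting, of which 67 were shared with it. The fold changes of all tested probe sets had a median of 9.29e-05 under quantile normalization and of 0.0147 under scaling to a common median. Without a filter on dim probe sets 8 were called, 4 higher and 4 lower, for 5 genes. That fit held 2184 probe sets at the floor on all arrays, which have no variance, and without those 31 were called. Without the trend of the variance 20 were called, 6 higher and 14 lower, for 14 genes. At an adjusted p of 0.10 there were 120, 56 higher and 64 lower, for 98 genes. With the arrays numbered 3 as a covariate there were 114, 62 of them lower, for 95 genes. With both of those arrays left out there were 38, 16 higher and 22 lower, for 30 genes, and 6 lists. With the Gapdh ratio as a covariate there were 100, of which 64 were shared with the reported 74, and 6 of the 32 named genes lost their call, with adjusted p-values up to 0.0748. Their log2 fold changes in that fit were 1.74 for Denn2b, 1.63 for Gadd45g, 0.83 for Creld2, -0.72 for Tk1, -0.87 for C2 and -1.40 for Per2, against 1.68, 1.56, 0.97, -0.76, -0.94 and -1.50. The lists of fatty acid synthesis and the proteasome lost theirs and oxidative phosphorylation gained one. With 1 array left out, calls ranged from 26 to 75, higher calls from 10 to 32, lower calls from 16 to 43, and genes from 21 to 58. Those fits have fewer arrays. For the others the cause was not tested. Of the 10 lists called, 2 were called with an estimated correlation and 3 by fry. The estimates were 0.008 for lipid droplets and -0.067 for the clock, under the preset 0.01. Their adjusted p-values in camera nevertheless rose, from 2.90e-11 to 0.0336 and from 0.00276 to 0.178. For these lists a higher correlation was therefore not the reason. The other called lists had estimates from 0.017 to 0.298. Of the 32 named genes, 29 lost their call without the filter, 19 without the trend, 15 with both arrays numbered 3 left out and 7 to 18 with 1 array left out. The cholesterol and lipid droplet lists were called in all 23 alternatives, the clock list in 22, fatty acid oxidation in 21, amino acid catabolism in 20, macrophages in 19, fatty acid synthesis in 15, acute phase in 14, the proteasome in 11 and glutathione in 9. With the replicate number as a block, 103 probe sets, 87 genes and 12 lists were called. Same-numbered arrays deviated together with correlations of 0.07, 0.11 and 0.31, and not every array correlated best with its own number. Correlations of differently numbered arrays ran from -0.21 to 0.11. The 3' to 5' ratios of Gapdh and pyruvate carboxylase ordered the arrays alike by number in both diets, and that of beta-actin did not. The pyruvate carboxylase ratio was 6.94, 7.96 and 2.62 on high-fat arrays 1, 2 and 3. On the low-fat arrays it was 3.78, 4.50 and 2.65. Whether the numbers pair the arrays, or only the arrays numbered 3 were alike, cannot be told from these values and stays open. The reported fit took no account of the numbers. With the block, pancreatic acinar cells and immediate early genes were the lists gained. Glucose metabolism was gained without probe sets with suffixes for shared probes or relaxed probe selection (adjusted p = 0.0255), and 7 lists without high-fat array 1. The robust estimate was not run for lists, where camera has no such setting, and no arrays were duplicates, so that alternative was not run. Signal near the floor limits the folds of dim genes such as Cidea on the low-fat diet.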

Other observations

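The splits of the arrays and the tests of collection time, of RNA quality, of mixed RNA and of shared tubulin probes were chosen after the data were seen, and the test of scaling used an alternative chosen before.

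Several changed genes outside the fixed rule were chosen after their values were seen. The largest rise of any probe set was that of 99671_at, which the gene table used does not list, at 5531 ± 3384 (SD, n = 3) on the high-fat diet against 174 ± 71.9 (SD, n = 3), 28.0-fold higher with an adjusted p of 0.00306. Among further rises were S100a10 (log2 fold change 1.22), Serpina12 (1.17), the carnitine acetyltransferase gene Crat (1.20), the glycerol phosphate dehydrogenase gene Gpd1 (0.84) and the transporter gene Abcg2 (0.83). Among further falls were Gch1 (-1.12), Txnip (-1.45) and Lifr (-1.44). Txnip has another probe set of opposite sign, and Lifr has a further one that fell (-1.32, adjusted p = 0.0135) and 2 others at 0.0066 and -0.0029. A second Lpl probe set rose with a log2 fold change of 1.58 and an adjusted p of 0.0499, while the brighter one had 1.23 and 0.0539. An Acaa1b probe set had 0.94 and 0.0203, while the brighter one, used for the gene, had 0.54 and 0.391.

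Pancreatic acinar transcripts varied between arrays of the same diet, in the same order by array number in both diets. Relative to all arrays, the list's mean was -0.15, 1.32 and -0.63 on high-fat arrays 1, 2 and 3. On the low-fat arrays it was -0.44, 0.61 and -0.70. The reason was not tested. Prss2 and Ctrb1 were chosen after their values were seen. Prss2 stood at 505, 2332 and 23.6 on the high-fat arrays 1, 2 and 3 and at 71.0, 982 and 32.0 on the low-fat arrays, and Ctrb1 at 1292, 3669 and 316.0 and at 682, 2410 and 183. The first principal component held 28.1% of the variance and the second, which set the arrays numbered 3 of both diets apart from the others, 26.4%.

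The number of probe sets called was 74 for the real grouping, and the highest number in any other split of the 6 arrays into 3 and 3 was 0. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

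The clock genes past the threshold, Dbp, Usp2 and Per2, all fell. All 4 tested members of opposite phase had a log2 fold change above 0, with a median of 0.53. All 8 output and period genes were below 0, with a median of -1.17, so the medians lay 1.70 apart. These groups were drawn up after the values were seen, and 0 of the 4 passed limma's threshold. The difference therefore decides nothing about a different time of day at collection. With the Gapdh 3' to 5' ratio as a covariate the median share of the fold of Dbp, Usp2 and Per2 that remained was 1.01. The adjusted p of Per2 moved to 0.0547 with a log2 fold change of -1.40 ± 0.27 (SE) in place of -1.50 ± 0.25 (SE), a smaller fold with a larger error. That ratio differed little between the diets, at 1.12 on the high-fat and 0.98 on the low-fat diet, so adjusting for it could remove little of a diet difference. The pyruvate carboxylase ratio was not used as a covariate. This fit therefore does not decide about RNA quality, which stays open. The time of collection is not given in the sources used here, so collection time and an effect of the diet on the clock cannot be told apart, and both stay open, the latter untested.

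High-fat array 1 showed smaller rises and smaller falls than the other high-fat arrays. On a scale where 0 is the low-fat mean and 1 the mean of the other high-fat arrays, over the probe sets called higher without the array in question, which differ between arrays, the medians were 0.68 for array 1 (30 of 33 below 1), 1.06 for array 2 (4 of 10) and 1.10 for array 3 (7 of 18), and over those called lower 0.71 (32 of 41), 0.96 (11 of 18) and 0.95 (17 of 29). Low-fat RNA mixed into the sample could give this. In array 1 the risen probe sets implied a low-fat share of 43.7% (quartiles 25.4% and 71.7%) and all 41 fallen ones 17.1% (quartiles 7.26% and 41.7%). The 33 fallen probe sets outside the cholesterol list implied 28.5% (quartiles 11.5% and 44.2%), and the 8 within it -3.54% (quartiles -7.25% and -2.53%). In array 3 the cholesterol probe sets also stood apart, at 9.09% against -5.64% for the other fallen and -16.4% for the risen ones. The cholesterol genes were singled out after the values were seen, so their quartiles alone do not decide the question. Mixed RNA would, however, add low-fat signal to every probe set. On array 1 Idi1 stood at 432 and Sqle at 178, against low-fat values of at least 4127 and 2107. Both lie below what a share of 28.5% or 43.7% would add by itself. For these genes that argues against mixing of such a size, and a smaller share of low-fat RNA stays open. Scaling is argued against: under quantile normalization the array stayed 0.398 below the mean of the others for rises. For falls its median was 0.70 against 0.97 and 0.93. Differences between the mice or their livers also stay open, and no biological explanation was tested.

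The beta-tubulin probe sets that rose were those of Tubb2a, Tubb3 and Tubb5, the last chosen after its value was seen (log2 fold change 0.99, adjusted p = 0.00676), and all carry a suffix for probes shared within a gene family. A rise of a single tubulin transcript may therefore read on these 3, though another Tubb3 probe set with that suffix, at 24.6 to 110.3 and so near the floor, had -0.27 and did not rise. Of the risen genes' tested probe sets, 2 have no such suffix but one for relaxed probe selection, and neither rose: the log2 fold changes were -0.09 for Tubb2a and 0.08 for Tubb5. This is consistent with probes shared between tubulin genes. How well those 2 probe sets read their transcripts was not tested, so separate rises stay open.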
